A study of Mus musculus with 3 samples.

How the data were processed

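Single-cell RNA sequencing was analysed from 3 libraries of sorted cells of the mouse small intestine, which form 1 group. Per the labels' protocols, the intestine without the duodenum came from wild-type C57Bl/6 females. The epithelium was stripped with EDTA and DTT, and the rest was digested warm with Liberase and DNase. The labels give all 3 libraries the same digestion time and temperature. Live cells negative for CD45 and positive for CD31 and podoplanin were sorted. Droplet libraries were made with 3′ chemistry. Each library is described as a pool of animals, and the labels do not say whether libraries shared animals. P-values therefore reach no further than these 3 libraries, whose spread may be technical. The edgeR fit also draws each gene's spread toward that of genes of similar level. Very small p-values thus do not rest on a gene's own spread among 3 libraries alone. The deposited matrices hold whole-number UMI counts per gene and barcode, not normalised. Per the submitters' processing notes, bcl2fastq 2.2, Cell Ranger 6.1.2 and the mm10 build were used, and the annotation release is not given in the sources used here.

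Barcodes with at least 500 detected genes and at most 15% mitochondrial UMIs were kept. Scrublet in scanpy 1.11.5 marked 4, 4 and 1 cells as doublets, or 0.0629%, 0.0596% and 0.0106%, against expected shares of 5.09%, 5.37% and 7.57%. Whether doublets were rare, missed, or removed before deposit is open, and removal of the expected share by score was added after the data were seen. Variable genes (2000), 30 principal components, 20 neighbours and Leiden clustering (leidenalg 0.10.2, resolution 1) gave 24 clusters of 22525 cells. The 328 genes of the 16 gene lists were kept out of the clustering genes. The lists, the cell type markers, the tests and the rule for named genes were fixed before the data were examined. A cluster was named after the class with the highest mean marker level. Its 10 leading genes were ranked against the cells of clusters whose highest class differed. It got no name when none of these genes was a marker of its class, or when another class had more markers among them. It also got none when fewer than 3 markers were detected. The same held when its cells were shallow and no marker led it in a second ranking, against all other cells. Interferon genes and the immediate early list were passed over in both rankings, a choice made after the clusters were seen. LEC-like stands for lymphatic and BEC-like for blood endothelial cells. LEC-like cells were clustered again into 13 sub-clusters, numbered by size. Names rest on rebuilt clusters and not on a deposited annotation.

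Counts were summed per library and class where each of the 3 sums held at least 20 cells. The sums were tested with edgeR 4.0.16 in R 4.3.3 (filterByExpr, TMM, glmQLFit, glmQLFTest) with the library as a block, since both sums of a library come from the same pool of animals and the same run. P-values were adjusted by Benjamini-Hochberg at a threshold of 0.05 over the reported genes, which are neither clustering genes nor class markers. Because the classes were made from the same cells, genes that go along with the clustering genes can pass without a separate cause. Lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01 and with an estimated correlation. Camera set each list against the other reported genes, which lacked the clustering genes, chosen as the most variable. List genes could not be clustering genes, so the lists kept their variable members apart from class markers. This can favour the lists in camera. Named genes had to pass the threshold with the same sign in all 3 libraries and reach 20 CPM in the higher class. From each list the gene with the largest fold in each direction was taken (at most 20 between sub-clusters), with 3 more in each direction outside the lists. Not every gene that this rule chose is named. Ccl21a, Rspo3, Wnt2, Plvap, Cd36, Vegfc, Ackr4, Madcam1, Fos and Klf2 were always named, and Ptprc, Pecam1, Pdpn and Prox1 as a check of the sort. CPM has its usual meaning and was taken over all UMIs of a sum. Levels are mean ± SD over the 3 libraries. Log2 fold changes carry an approximate standard error, taken as the absolute log2 fold change over the square root of the edgeR F statistic. It was not fitted directly and may understate the counting error of genes with few UMIs. Intervals on shares are exact 95% binomial intervals that cover counting error only. A fold against 0 UMIs was computed against 3 UMIs over the group.

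The test was tried on simulated counts with 200 changed genes. These were drawn from the fitted dispersions, with no library effect and no clustering step. The calls of unchanged genes therefore do not measure the error rate in the real data. For LEC-like against BEC-like cells, over 12921 genes, it recovered 44.2% of the tested genes changed by 1 and 78.1% of those changed by 2 on the log2 scale, with 5 unchanged genes called. For sub-clusters 1 and 2, over 11481 genes, the shares were 91.9% and 99.0%, with 8 unchanged genes called. Other settings tried were the cell filters, doublet removal, the clustering resolution, list genes in the clustering, each library left out, no block, RLE size factors, DESeq2 1.42.0, no gene filter, cells thinned to 3000 UMIs and equal cell numbers. Positions are from GENCODE M21 on GRCm38, the assembly of mm10, matched by gene identifier for 457 of 458 list and marker genes. Mmrn1, a lymphatic marker, had 0 UMIs in all 24541 barcodes and could not serve. BEC-like vein, artery and capillary cells were not tested against each other, because the sub-clusters held too few cells in a library.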

Results

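The data were UMI counts from 3 libraries of 1 group of sorted small intestinal cells, so the comparisons lie between cell classes within libraries. The files held 24541 barcodes and 32285 genes. Libraries 1, 2 and 3 had 6931, 7678 and 9932 barcodes with totals of 58857545, 69231794 and 74571090 UMIs. The filters removed 572, 971 and 464 barcodes, and the analysed cells had median counts of 7978, 7261 and 6698 UMIs. The libraries were not copies of each other, since the chi-square statistic of their LEC-like sums over its degrees of freedom was 77.5, 84.4 and 22.0 for the 3 pairs.

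The first question was which cells a sort for CD31 and podoplanin, a membrane protein of lymphatic endothelium, had captured. Lymphatic endothelial (LEC-like) cells made up 83.4% ± 10.5 of the analysed cells (SD, n = 3), and blood endothelial (BEC-like) cells 0.940% ± 0.587. The LEC-like share was 90.1% in library 1 (interval 89.4 to 90.9), 71.4% in library 2 (70.3 to 72.5) and 88.8% in library 3 (88.2 to 89.4). Library 2 stood apart, with 7.67% epithelial cells against 2.23% and 1.56% in the others (mean 3.82% ± 3.35). Fibroblasts formed 1.76% ± 1.05, mural or smooth muscle cells 1.62% ± 1.40, myeloid cells 1.43% ± 1.06 and proliferating cells 1.17% ± 0.230. T or innate lymphoid cells formed 0.794% ± 0.466, B or plasma cells 0.566% ± 0.378, glia or neurons 0.159% ± 0.123 and cells without a name 4.29% ± 2.30. Without library 2 the means were 1.90% epithelial, 0.827% mural or smooth muscle, 0.881% myeloid, 0.605% BEC-like, 0.364% B or plasma cells and 0.0896% glia or neurons. The sort gate can set these shares. Proliferating cells were mostly LEC, with Prox1 in 75.9% of them after thinning to 3000 UMIs.

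As a check of the gate, cells were thinned to 3000 UMIs. Pdpn, the gene of podoplanin, was then seen in 50.3% of LEC-like and 3.47% of BEC-like cells, against 4.13% of B or plasma cells, taken as cells that should lack it. Unthinned, the shares were 75.4%, 9.95% and 13.4% at median depths of 7073, 5725 and 21140 UMIs, and thinning left out 597, 28 and 6 cells. Pdpn in BEC-like cells thus lay at the background level. Ptprc, the gene of CD45, was seen in 0.115% of LEC-like cells after thinning (0.196% unthinned), 0.270% of epithelial cells, taken as background, and 82.8% of T or innate lymphoid cells.

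**Figure D1:**
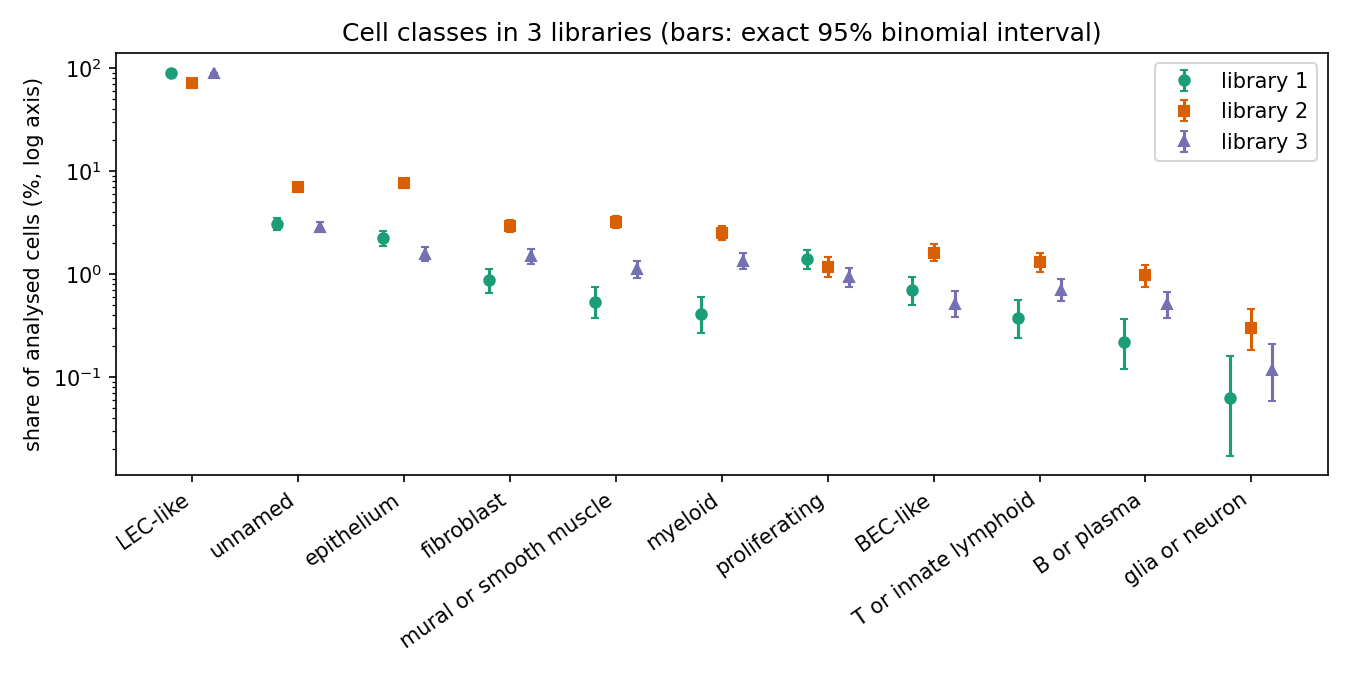
Share of analysed cells per class in percent on a log axis, with a point for each of the 3 libraries and exact 95% binomial intervals as bars. LEC-like cells hold 71.4% to 90.1%, and library 2 has the highest epithelial share, 7.67%.

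The comparison of LEC-like with BEC-like cells asked what separates lymphatic from blood endothelium within this sort. LEC-like cells had more of the chemokine Ccl21a (chromosome 4, 42772860 to 42773993, GRCm38), which guides dendritic cells and T cells, and of Rspo3 and Wnt2, ligands that act on intestinal stem cells through Wnt signalling. BEC-like cells had more of Plvap (chromosome 8, 71497765 to 71511752), which forms the diaphragms of fenestrae, of the fatty acid handling genes Fabp5 and Cd36, and of the VEGF co-receptor Nrp1. Ccl21a stood at 10656 ± 1211 CPM in LEC-like and 935 ± 515 CPM in BEC-like cells, an 11.4-fold difference, but its near-identical copies make its count uncertain. Plvap stood at 7.64 ± 1.68 CPM in LEC-like and 3151 ± 299 CPM in BEC-like cells, a 413-fold difference. Of 11938 reported genes, 2940 passed, 1494 higher in LEC-like and 1446 higher in BEC-like cells, and 1826 of them exceeded 1 on the log2 scale. The count was 1241 without library 2, which held 108 of the 201 BEC-like cells, 1653 in thinned cells and 1519 with equal cell numbers. DESeq2 called 780 genes higher in LEC-like and 1191 higher in BEC-like cells.

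BEC-like cells held some RNA of LEC genes, which stands beside every gene higher in LEC-like cells. Prox1, the transcription factor of lymphatic identity, stood at 784 ± 97.9 and 86.4 ± 30.1 CPM in LEC-like and BEC-like cells, a 9.08-fold difference. Ccl21a differed 11.4-fold, Rspo3 7.15-fold and Wnt2 18.1-fold, so the Rspo3 UMIs in BEC-like cells were near the share that Prox1 gave. Most of these UMIs lay in the 34 cells of a BEC-like sub-cluster led by Lyve1 and Ccl21a, with 52 of 73 Rspo3 UMIs and 13 of 20 Wnt2 UMIs. Without that sub-cluster, a setting chosen after the data were seen, the log2 fold change was 4.13 for Rspo3 (with it 2.76), 4.73 for Wnt2 (3.68), 5.48 for Ccl21a (3.61) and 4.23 for Prox1 (3.05). With that setting edgeR called 2620 genes, 1423 higher in LEC-like and 1197 in BEC-like cells. As further checks of the sort and not as findings, Pecam1 stood at 531 ± 17.8 and 1027 ± 133 CPM and Pdpn at 258 ± 8.56 and 15.2 ± 10.7 CPM, and Ptprc had 39 UMIs in LEC-like and 7 in BEC-like cells.

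Of 19 measured epithelial niche ligands, 6 were higher in LEC-like and 3 in BEC-like cells, and 10 missed the test. Rspo3 (chromosome 10, 29452416 to 29535867) stood at 302 ± 5.18 CPM in LEC-like and 42.2 ± 10.9 CPM in BEC-like cells (log2 fold change 2.76 ± 0.19, edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 1.54e-45, higher in 3 of 3 libraries). Wnt2 (chromosome 6, 17988940 to 18030585) stood at 156 ± 1.71 CPM and 8.61 ± 7.98 CPM, with a log2 fold change of 3.68 ± 0.26 that was 4.90 without library 2. The alarmin Il33, chosen after its values were seen, stood at 427 ± 26.0 CPM and 60.2 ± 27.5 CPM. Among the named classes with enough cells, Rspo3 and Wnt2 had their highest mean in LEC-like cells, and the shallow unnamed cluster 11 had 163 ± 4.01 CPM of Wnt2. Rspo3 in fibroblasts was 34.9% of its LEC-like level and Prox1 8.98%, so free RNA at 1 share would not give the former. Fibroblasts had 105 ± 15.9 CPM of Rspo3 and 469 ± 8.17 CPM of Bmp4, and mural or smooth muscle cells had 368 ± 56.3 CPM of the BMP antagonist Grem1.

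**Figure D2:**
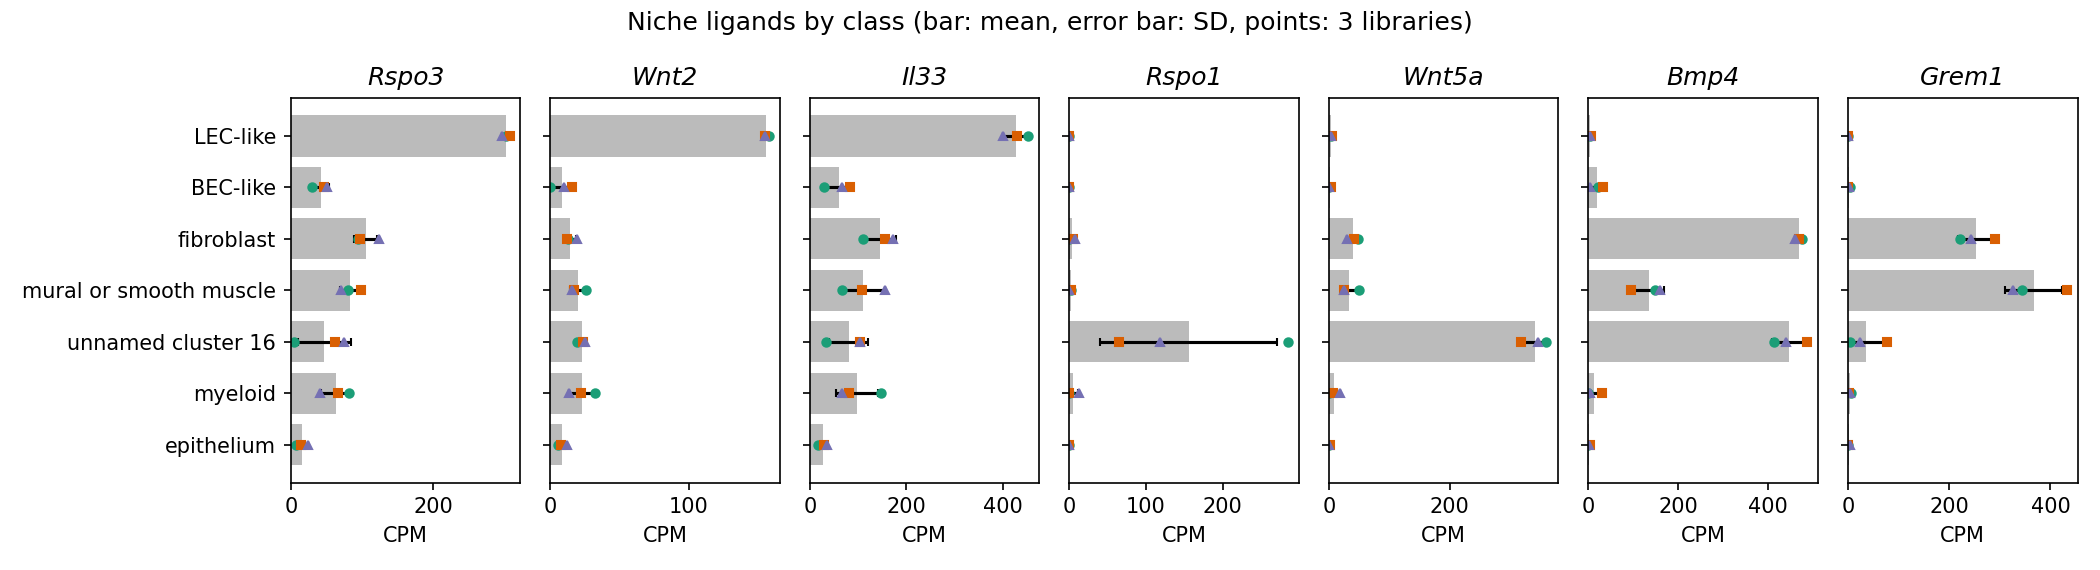
CPM of 7 niche ligands in 7 cell classes, with bars for the mean, error bars for the SD and points for the 3 libraries. Rspo3 reaches 302 CPM and Wnt2 156 CPM in LEC-like cells, and Bmp4 reaches 469 CPM in fibroblasts.

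Of 25 measured chemokine and leukocyte traffic genes, 9 were higher in LEC-like and 10 in BEC-like cells. Madcam1, a receptor for gut-homing lymphocytes, stood at 358 ± 164 CPM in BEC-like cells (log2 fold change -11.29 ± 0.24). Ackr4, a scavenging receptor for CCL21, was too low in both classes to be tested. Of 21 lipid handling genes, 5 were higher in LEC-like and 8 in BEC-like cells. Fabp5 was 78.6-fold and Cd36 17.2-fold higher in BEC-like cells, and Vldlr stood at 131 ± 17.9 CPM in LEC-like and 9.35 ± 10.9 CPM in BEC-like cells. Of 20 genes for fenestrae, caveolae and transport, 12 were higher in BEC-like and 5 in LEC-like cells, with the water channel gene Aqp1 at 2117 ± 151 CPM and 5.49-fold higher in LEC-like cells. Of 18 junction genes, 9 were higher in BEC-like and 3 in LEC-like cells. The connexin gene Gja5, known from arteries, had 0 UMIs in LEC-like and 42 in BEC-like cells, at least 1223-fold higher in the latter. Without library 2, the log2 fold change of Vldlr was 5.30 in place of 3.07, and Gja5 was too low to be tested.

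Of 18 measured VEGF, angiopoietin and adrenomedullin genes, 7 were higher in BEC-like and 4 in LEC-like cells. Nrp1 stood at 674 ± 199.7 CPM (log2 fold change -11.62 ± 0.22) and the lymphangiogenic factor gene Vegfc at 81.8 ± 26.2 CPM (log2 fold change -7.49 ± 0.43) in BEC-like cells, and Pgf was 6.32-fold higher in LEC-like cells. Of 16 Notch genes, 8 were higher in BEC-like and 3 in LEC-like cells. The fringe enzymes, which modify Notch, parted, with Mfng at -8.88 ± 0.72 and Lfng at 2.03 ± 0.32 on the log2 scale. Of 16 BMP and TGF-beta genes, 10 were higher in BEC-like cells, among them the inhibitor Smad6 (-8.29 ± 0.77 on the log2 scale), and 5 in LEC-like cells. Gdf15 was 3.02-fold higher in LEC-like cells, a call lost without library 2 (edgeR adjusted p = 0.116), without library 3 (adjusted p = 0.0906), with no replicate block, in DESeq2 and in thinned cells, with a range of 0.00170 to 0.356 over the settings tried. Without library 2 the log2 fold changes were 3.77 for Pgf (with all libraries 2.05), 2.39 for Gdf15 (1.20) and -10.15 for Smad6, which had -7.17 without library 1.

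Of 24 basement membrane and matrix genes, 13 were higher in BEC-like cells, among them Col15a1 at 520.2 ± 256 CPM, and 7 in LEC-like cells, among them Emilin1 at 208 ± 35.6 CPM. Of 17 coagulation and complement genes, 7 were higher in LEC-like and 7 in BEC-like cells. F8, the gene of coagulation factor VIII, had 3342 against 2 UMIs, a pooled ratio of 19.1 with a counting interval of 5.29 to 158, in favour of LEC-like cells. C1qtnf9 had 195 against 3 UMIs, a pooled ratio of 5677 with a counting interval of 1914 to 27768, in favour of BEC-like cells. Of 19 guidance genes, 9 were higher in BEC-like cells, among them Epha4 (81.1-fold), and 5 in LEC-like cells, among them Sema3a (24.0-fold). Of 15 flow sensing genes, 5 were higher in BEC-like cells, among them Edn1 (73.1-fold) and Klf2 (1.86-fold), and 3 in LEC-like cells, among them Nfatc1 (2.46-fold). Of 7 prostanoid genes, 2 were higher in LEC-like and 2 in BEC-like cells, among the latter the cyclooxygenase gene Ptgs1 (299-fold). Without library 2, F8 and Sema3a had 0 UMIs in BEC-like cells and the log2 fold change of Emilin1 was 3.94 in place of 2.75. Without library 1, that of Col15a1 was -10.35 in place of -11.09.

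Of 15 glycolysis genes, 7 were higher in BEC-like cells, among them Ldha (3.66-fold), and 1 in LEC-like cells, Pfkfb3 (1.63-fold). The Pfkfb3 call was lost without library 1 (edgeR adjusted p = 0.0840) and without library 2 (adjusted p = 0.0891), with a range of 0.00400 to 0.111 over the settings tried. It was also lost with no replicate block, in DESeq2, in thinned cells, at resolution 1.5, with doublets kept and with doublets removed by score. Of 27 antigen presentation and interferon genes, 11 were higher in LEC-like and 5 in BEC-like cells, among them Ifit1 (3.09-fold). Of 21 immediate early and dissociation genes, 10 were higher in LEC-like and 8 in BEC-like cells. Fos stood at 5398 ± 815 and 3125 ± 284 CPM, Hspa1b, whose near-identical copy Hspa1a makes its count uncertain, was 4.80-fold higher in LEC-like cells, and Ier3 was 4.53-fold higher in BEC-like cells. Outside the lists, Flnc stood at 81.5 ± 9.07 and 4.53 ± 1.71 CPM. Lrrn2 had 3987 against 1 UMIs, a pooled ratio of 45.6 with a counting interval of 8.19 to 1803, and Pacsin3 had 3050 against 1 UMIs, a pooled ratio of 34.9 with a counting interval of 6.26 to 1379.7, both in favour of LEC-like cells. Cytl1 had 287 against 3 UMIs, a pooled ratio of 8356 with a counting interval of 2831 to 40756, Cadm3 had 103 against 1 UMIs, a pooled ratio of 8996 with a counting interval of 1579 to 358739, and Myrip had 52 against 1 UMIs, a pooled ratio of 4542 with a counting interval of 780.0 to 182798, all in favour of BEC-like cells. Without library 2, Lrrn2 and Pacsin3 had 0 UMIs in BEC-like cells, Cytl1 had 0 in LEC-like cells, Cadm3 and Myrip were too low to be tested, and the log2 fold change of Flnc was 4.61. Without library 1, Myrip had 0 UMIs in LEC-like cells.

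Adjusted over the list alone, the genes that passed in edgeR numbered 18 for antigen presentation, 22 for matrix, 16 for BMP and TGF-beta, 12 for junctions, 20 for chemokines, 15 for coagulation, 11 for niche ligands, 17 for transport, 8 for flow sensing, 8 for glycolysis, 14 for guidance, 19 for immediate early, 13 for lipid handling, 11 for Notch, 5 for prostanoids and 12 for VEGF. Camera at the preset correlation put 7 lists past the threshold, all toward BEC-like cells: matrix, BMP and TGF-beta, junctions, transport, glycolysis, lipid handling and Notch. With an estimated correlation none of the 16 passed in camera, and 0 had an unadjusted p under 0.05. The adjusted p with an estimated correlation was 0.386 for matrix, BMP and TGF-beta, junctions, transport, lipid handling and Notch and 0.421 for glycolysis.

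**Figure D3:**
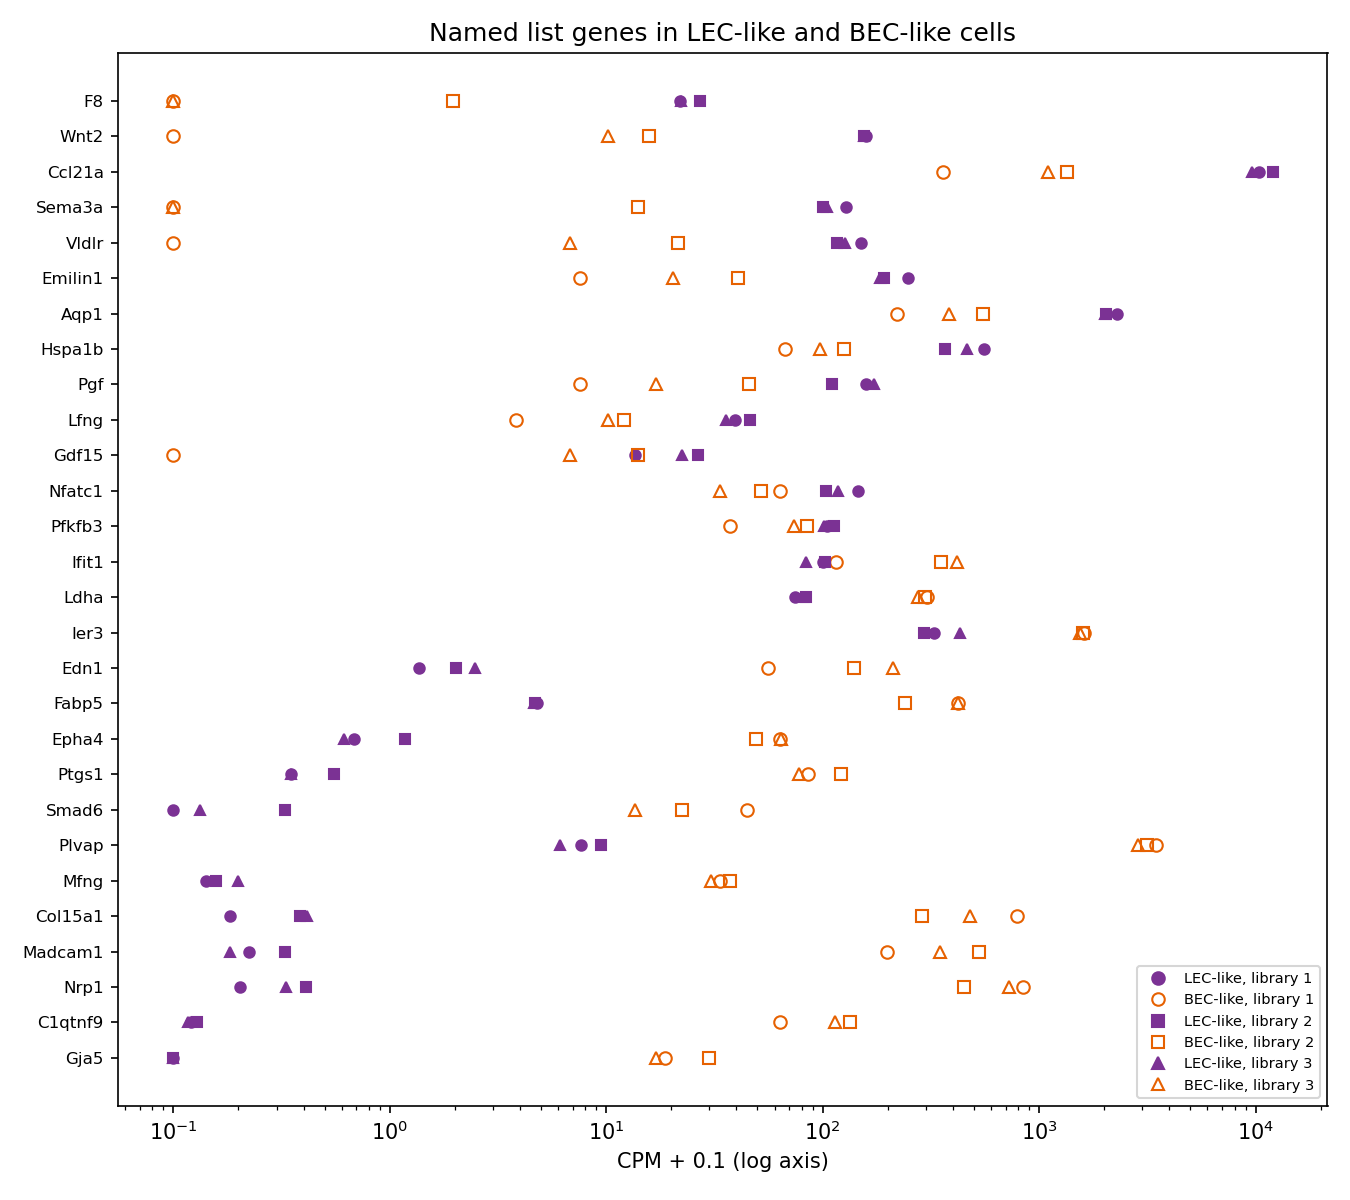
CPM plus 0.1 on a log axis of named list genes in LEC-like and BEC-like cells, with a symbol for each of the 3 libraries. Plvap averages 3151 CPM in BEC-like and 7.64 CPM in LEC-like cells.

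BEC-like cells split into 4 sub-clusters of 116, 34, 34 and 17 cells, too few per library for a test, so pooled values are given. The first was capillary-like, with a mean level of the capillary markers of 399.9 CPM, against 202, 76.0 and 226 CPM in the others. The third was vein-like, with 712 UMIs of Madcam1 (1283 CPM) and 520 of the leukocyte adhesion gene Sele, and 27 of its cells came from library 2. The fourth was artery-like, with Gja5 at 236 CPM. The second was led by the LEC genes Lyve1 and Ccl21a and the mural gene Rgs5 and got no name.

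No LEC sub-cluster could be named capillary or collecting and valve by its leading genes, which held no collecting or valve marker and 1 capillary marker, Itih5 in sub-cluster 6. Some markers, chosen after their values were seen and not tested, parted sub-clusters 1, 3, 5 and 8 from sub-clusters 2, 4, 6 and 7. Pooled over libraries, the capillary marker Itih5 had 64.1, 60.3, 76.2 and 115 CPM in the former and 271, 200.3, 354 and 202 CPM in the latter. The collecting or valve markers Cldn11 and Foxc2 went the other way, with 25.8, 29.9, 25.0 and 29.8 against 13.1, 10.98, 13.6 and 11.6 CPM for Cldn11 and 20.1, 22.1, 22.4 and 18.6 against 16.5, 17.9, 15.9 and 16.3 CPM for Foxc2. The capillary marker Lyve1 mostly went against Itih5, with 4485, 4734, 4210.3 and 5180.4 CPM in the former and 3949.9, 4342, 3728 and 3830.3 CPM in the latter. Sub-cluster 9 lay between these groups, with 129 CPM of Itih5 and 15.8 CPM of Cldn11. The directions of the other capillary and collecting or valve markers are not given here, so these values do not set a capillary type against a collecting type. The largest sub-clusters, 1 with 2844 and 2 with 2758 cells, were compared. Sub-cluster 1 had more Tgfbi, a matrix protein induced by TGF-beta (17.8-fold), and more Cd36, a fatty acid transporter (1.91-fold). Sub-cluster 2 had more of the inducible cyclooxygenase gene Ptgs2 (8.19-fold), of the chemokine Cxcl9 (6.12-fold) and of most antigen presentation genes. The Ptgs2 log2 fold change was -2.72 ± 0.20, and -3.58 without library 3. Pooled over libraries, Ptgs2 stood at 72.6 CPM in sub-cluster 2 and 9.08 CPM in sub-cluster 1. In sub-clusters 4, 6 and 7 it stood at 7.61, 2.11 and 8.82 CPM, and in sub-clusters 3, 5 and 8 at 1.92, 0.460 and 0.466 CPM. The high Ptgs2 level of sub-cluster 2 was thus not shared by sub-clusters 4, 6 and 7. Of 9875 reported genes, 2890 passed, 1528 higher in sub-cluster 1 and 1362 in sub-cluster 2, and 244 of them exceeded 1 on the log2 scale. The count was 1290 with no replicate block, 1137 in DESeq2 and 1670 in thinned cells. The libraries gave 601, 765 and 1478 cells to sub-cluster 1 and 1341, 455 and 962 to sub-cluster 2.

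Of 27 antigen presentation and interferon genes, 20 were higher in sub-cluster 2 and 2 in sub-cluster 1. Cd74, the invariant chain of MHC class II, stood at 92.2 ± 54.7 CPM in sub-cluster 1 and 229.7 ± 116 CPM in sub-cluster 2 (log2 fold change -1.27 ± 0.06, edgeR adjusted p = 1.51e-12, higher in sub-cluster 2 in 3 of 3 libraries), a call lost with no replicate block (adjusted p = 0.102, the highest of the settings tried, with a lowest of 1.46e-109). Of 23 chemokine and traffic genes, 12 were higher in sub-cluster 2 and 5 in sub-cluster 1. Of 15 BMP and TGF-beta genes, 9 were higher in sub-cluster 1, led by Tgfbi (chromosome 13, 56609523 to 56639562) with 72.3 ± 16.3 CPM against 4.07 ± 0.333 CPM, and 2 in sub-cluster 2. Of 3 prostanoid genes, 1 was higher in sub-cluster 2 (Ptgs2) and 2 in sub-cluster 1, among them Ptges (1.84-fold). Of 12 VEGF genes, 7 were higher in sub-cluster 2, among them Pgf (2.05-fold), and 3 in sub-cluster 1. Of 17 guidance genes, 7 were higher in sub-cluster 2, among them Plxnd1 (2.83-fold), and 3 in sub-cluster 1, among them Efnb2 (1.66-fold). The guidance list's median of -0.26 and mean of 0.12 differed in sign, and its test pointed to sub-cluster 2. So did the test of the prostanoid list, which had a median of 0.68 and a mean of -0.37 and missed the threshold (camera adjusted p = 0.309).

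Of 19 lipid handling genes, 7 were higher in sub-cluster 2, among them Fabp4 (1.84-fold), and 5 in sub-cluster 1. Of 19 matrix genes, 11 were higher in sub-cluster 2, among them Emilin1 (1.94-fold), and 4 in sub-cluster 1, among them Bgn (2.27-fold). Of 19 transport genes, 7 were higher in sub-cluster 1, among them the prostaglandin transporter gene Slco2a1 (9.50-fold), and 5 in sub-cluster 2. Of 13 coagulation genes, 7 were higher in sub-cluster 1, among them Plat (3.11-fold), and 3 in sub-cluster 2, among them F8 (2.34-fold). Of 15 Notch genes, 6 were higher in sub-cluster 2, among them Heyl (3.65-fold), and 3 in sub-cluster 1, among them Lfng (1.81-fold). Of 15 junction genes, 6 were higher in sub-cluster 1 and 3 in sub-cluster 2. Of 15 flow sensing genes, 7 were higher in sub-cluster 1, among them Foxc1 (1.65-fold), and 2 in sub-cluster 2. Of 15 niche ligands, 6 were higher in sub-cluster 1 and 4 in sub-cluster 2, and of 15 glycolysis genes 7 and 2.

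Of 21 immediate early genes, 8 were higher in sub-cluster 1, among them Socs3 (1.72-fold), and 5 in sub-cluster 2. Fos differed by 0.23 ± 0.03 and Klf2 by 0.30 ± 0.05 on the log2 scale, calls lost with no replicate block (edgeR adjusted p = 0.222 and 0.390). Over the settings tried the adjusted p ranged from 3.96e-20 to 0.222 for Fos, whose call was also lost at resolution 1.5, and from 6.62e-23 to 0.390 for Klf2, whose call was also lost in DESeq2 and whose value was 0.19 without library 3. Outside the lists, the rule for named genes chose Mboat1, Fxyd6 and Znhit3 for sub-cluster 1, with log2 fold changes of 1.04 ± 0.09, 1.01 ± 0.04 and 1.00 ± 0.09. For sub-cluster 2 it chose Srgap1, Glipr2 and Prag1, with -1.88 ± 0.13, -1.61 ± 0.14 and -1.46 ± 0.12. These are not the strongest differences, since the rule passed over clustering genes. Against all other LEC-like cells, sub-cluster 1 was led by Nts, Selp and Cdkn1a and sub-cluster 2 by Ptgs2, Egr4 and Odc1. Over 1 on the log2 scale were 495 of all tested genes, against 244 of the reported genes. Ccl21a differed by 0.12 ± 0.03, a call lost without library 1 (edgeR adjusted p = 0.0659), with no replicate block and in DESeq2, with a range of 1.21e-08 to 0.601. Rspo3 stood at 271 ± 1.30 and 281 ± 16.1 CPM (edgeR adjusted p = 0.824), Wnt2 at 117 ± 2.34 and 129 ± 9.94 CPM (adjusted p = 0.328) and Plvap at 7.96 ± 2.28 and 9.49 ± 2.28 CPM (adjusted p = 0.359), all short of the threshold. Vegfc, Ackr4, Madcam1 and Ptprc were too low to be tested. The sort check gave Pdpn at 188 ± 18.1 and 190.5 ± 14.5 CPM, Pecam1 at 462 ± 42.7 and 450.2 ± 19.1 CPM and Prox1 at 785 ± 119 and 885 ± 107 CPM.

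Adjusted over the list alone, the genes that passed between sub-clusters 1 and 2 in edgeR numbered 23 for antigen presentation, 17 for matrix, 11 for BMP and TGF-beta, 12 for junctions, 19 for chemokines, 10 for coagulation, 11 for niche ligands, 12 for transport, 10 for flow sensing, 9 for glycolysis, 10 for guidance, 13 for immediate early, 12 for lipid handling, 9 for Notch, 3 for prostanoids and 10 for VEGF. Camera at the preset correlation put 7 lists past the threshold, BMP and TGF-beta and coagulation toward sub-cluster 1 and antigen presentation, matrix, chemokines, guidance and VEGF toward sub-cluster 2. With an estimated correlation none passed in camera, and 2 had an unadjusted p under 0.05. The adjusted p with an estimated correlation was 0.286 for BMP and TGF-beta, antigen presentation and chemokines and 0.318 for coagulation, matrix, guidance and VEGF.

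**Figure D4:**
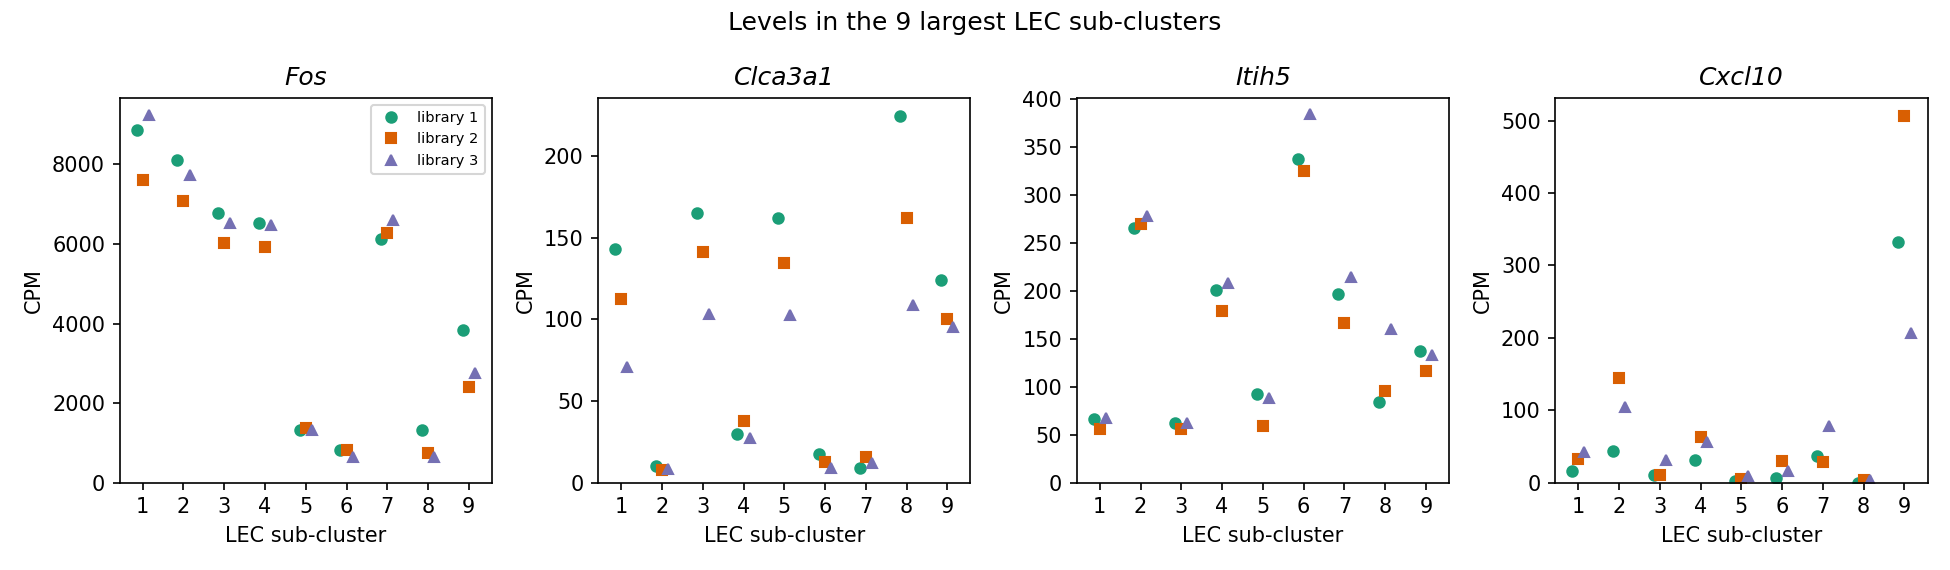
CPM of 4 genes in the 9 largest LEC sub-clusters, with a symbol for each of the 3 libraries. Fos averages 8565 ± 860.3 CPM in sub-cluster 1 and 766 ± 97.1 CPM in sub-cluster 6.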

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

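The tests of where LEC marker UMIs in BEC-like cells came from were chosen only after those levels were seen.

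Signals lay in cells and barcodes that no comparison used. Any count above 0 brought them here, so no test stands behind them. Cluster 17 had 220 cells (48, 122 and 50 per library), led by the Paneth cell defensins Defa21, Defa22 and Defa30, which share near-identical copies, and defensins took 0.920%, 25.4% and 17.6% of its UMIs. After thinning, the lymphatic marker Lyve1 was seen in 89.3% and Prox1 in 70.7% of its cells, against 20.0% and 10.9% of epithelial cells, so the cluster held both programmes. Cluster 16 had 239 cells led by Ogn, Slpi and the fibroblast marker Pdgfra, with Pdpn in 53.0% of them after thinning. Its highest class was mesothelium, with 5 markers detected, but none of these was among its leading genes, so its cell type is open. Cluster 11 had 473 cells led by Sned1, Reln and Ushbp1, with a median of 1405 UMIs. Its highest class was LEC, and it got no name because its cells were shallow and no LEC marker led it against all other cells. Unthinned, Lyve1 was seen in 91.8% and Prox1 in 60.0% of its cells, which the LEC-like share does not count. The barcodes removed by the filters held 879 UMIs of Prox1, 251, 398 and 230 per library, and mitochondrial genes took 51.5%, 36.5% and 34.6% of their UMIs.

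LEC marker UMIs in BEC-like cells were unevenly spread. The 20 of 201 BEC-like cells richest in them held 73.3% of these UMIs, against at most 19.3% in 1000 allocations in proportion to cell depth, which argues against free RNA at a constant share as the whole source. These cells had 2.19 times the relative UMI count of the others and a median doublet score of 0.179 against 0.0791, so droplets that held a LEC and a BEC may be a source. The design names no group that would give a biological explanation, and none was tested.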

How the results depend on the processing

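The tests of doublets removed by score, of BEC-like cells without the sub-cluster led by LEC genes, and of the low-Fos pair were chosen after the data were seen. Mean shares moved by less than 1 SD under each setting, with 80.1 to 89.5% LEC-like and 0.605 to 1.15% BEC-like cells when a library was left out. Named genes of LEC-like against BEC-like cells kept direction and side of the threshold in 714 values and lost the call in 13, from Gdf15 and Pfkfb3. Between sub-clusters 1 and 2 the numbers were 525 and 8, with 11 changes of sign, and in the low-Fos pair 482 and 8, with 14 calls gained and 8 changes of sign. Where cells were clustered anew, the matched sub-clusters held partly other cells. The overlap, shared over combined cells, fell to 0.445 for sub-clusters 1 and 2 at resolution 0.5. In the low-Fos pair it fell to 0.299 with list genes in the clustering. Thinning and equal cell numbers leave fewer UMIs, and a library left out leaves fewer sums. The cause of the other shifts was not tested. Thinning, which also dropped cells under 3000 UMIs, lowered the count in each comparison, and how much of that is due to depth was not tested.

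For LEC-like against BEC-like cells, thinning gave 1653 genes (875 higher in LEC-like, 778 in BEC-like), equal cell numbers 1519 (675 and 844, with 896 over 1 on the log2 scale), DESeq2 780 higher in LEC-like cells, and no replicate block 2994. A library left out gave 1241 to 2581 genes, 606 to 1349 higher in LEC-like, 635 to 1232 in BEC-like and 1016 to 1539 over 1.

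For sub-clusters 1 and 2, no replicate block gave 1290 genes (683 and 607), DESeq2 1137 (632 and 505, with 137 over 1 on the log2 scale) and thinning 1670 (912 and 758). Over 1 were 495 of all tested genes and 380 at resolution 1.5. A library left out gave 2067 to 2636 genes, 1088 to 1391 and 979 to 1245 by direction and 206 to 249 over 1.

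For the low-Fos pair, no replicate block gave 862 genes (394 and 468), DESeq2 480 (228 and 252, with 78 over 1), thinning 888 (424 and 464, with 114 over 1), and all tested genes 1249 higher in sub-cluster 8 and 381 over 1. A library left out gave 1111 to 1359 genes, 517 to 674 and 594 to 685 by direction and 162 to 170 over 1. At resolution 0.5 both sub-clusters matched the same cluster, so no value was had.

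Lists past camera numbered 0 in each comparison with an estimated correlation (0, 2 and 2 at an unadjusted p under 0.05), and 8, 9 and 11 with no replicate block. Settings for BEC-like vein, artery and capillary cells were not run, because the sums were too small.

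Log2 fold changes short of the threshold changed sign. Between sub-clusters 1 and 2, Rspo3 had -0.015 with at least 1000 genes per cell, -0.00011 with doublets kept, -0.013 with list genes in the clustering and -0.0059 when thinned. Wnt2 had 0.025 at resolution 1.5. Plvap had 0.15 with at most 8% mitochondrial UMIs, 0.29 at resolution 1.5, 0.00013 with doublets removed by score and 0.058 when thinned. With a library left out, Rspo3 ranged from -0.0441 to 0.0516 and Wnt2 from -0.143 to 0.00918. In the low-Fos pair, Ccl21a had -0.079, Fos -0.64 and Klf2 -0.46 with doublets removed by score, Fos -0.12 with at least 1000 genes per cell, and Rspo3 0.0061 when thinned. With a library left out, Ccl21a ranged from -0.00269 to 0.0383, Fos from -0.0985 to 0.352 and Klf2 from -0.127 to 0.297.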

Other observations

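The pair of sub-clusters with low Fos and the tests on it were chosen after the data were seen, as were the Fos ratio within libraries, the count of classes by the place of library 2 and the differences between libraries 1 and 2.

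Sub-cluster 9 of the LEC-like cells, with 778 cells (4.20% ± 0.917 of LEC-like cells), was led by the interferon-induced genes Ifit3, Rsad2 and Ifit1, and had 348 ± 151 CPM of Cxcl10 and 177 ± 27.3 CPM of Cd274, the gene of PD-L1. Sub-cluster 11, with 151 cells, was led by the interferon-induced chemokine genes Cxcl9 (1095 CPM) and Cxcl10 (1602 CPM) and had 564 CPM of Cd274, pooled over libraries, which gave it 20, 24 and 107 cells. In sub-cluster 6 the pooled levels of these 3 genes were 14.9, 16.4 and 44.1 CPM. Sub-cluster 12, with 77 cells, was led by DNA replication genes such as Hells, Mcm5 and Mcm2. Sub-cluster 10 held 256 cells, 223 of them from library 2, and its leading genes came from several other cell types, with Igha, Igkc and Jchain of plasma cells, Fabp6, Reg3b, Reg3g, Fabp2 and Fabp1 of the epithelium, Dcn of fibroblasts and the Paneth cell defensin Defa24.

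The cells of the unnamed cluster 16 had 341 ± 21.0 CPM of Wnt5a, 447 ± 37.6 CPM of Bmp4, 156 ± 115 CPM of the niche ligand Rspo1 and 173 ± 66.8 CPM of Wnt4. In fibroblasts these genes stood at 39.8 ± 9.64 CPM, 469 ± 8.17 CPM, 3.94 ± 3.60 CPM and 135 ± 1.24 CPM. Rspo1 in the 3 libraries of cluster 16 was 285, 64.2 and 118 CPM.

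Fos averaged 8565 ± 860.3 CPM in sub-cluster 1 and 766 ± 97.1 CPM in sub-cluster 6. Within each library sub-cluster 1 had at least 9.18 times the Fos of sub-cluster 6, so the difference was present within libraries. Sub-clusters 1 and 6 had the highest and lowest pooled Fos of the LEC sub-clusters and were chosen after the data were seen. A high ratio followed largely from that choice. Handling to which cells of a library respond unequally could give it too, so the ratio cannot tell whether handling caused the difference. Between libraries, the mean log2 CPM of the immediate early list in LEC-like cells was lowest in library 2 and highest in library 1. Handling alike for all cells of a library would give most other classes that order, and 1 of 6 had it (5 classes had been foreseen). That count met the bound set beforehand against such handling, but the bound was too strict, since it took a change of place of libraries 1 and 3 for a different order, and library 2 was lowest in 4 of the 6 classes.

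Between libraries 1 and 2 the log2 difference of the list's summed CPM was 0.41 in LEC-like, 0.49 in mural or smooth muscle, 0.09 in epithelial and -0.19 in T or innate lymphoid cells. Intervals from resampled cells, which cover cell sampling only, included 0 in each of the 6 other classes. For the difference between libraries, handling and LEC states cannot be told apart with 3 libraries.

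The pair of LEC sub-clusters with at least 1000 cells and the lowest Fos was sub-cluster 8 with 1176 and sub-cluster 6 with 2079 cells. Of 9244 reported genes 1678 passed in edgeR, 827 higher in sub-cluster 8 and 851 in sub-cluster 6, and 1111 without library 3. Tgfbi stood at 74.1 ± 20.3 CPM in sub-cluster 8 and 3.07 ± 1.87 CPM in sub-cluster 6. Of 27 antigen presentation and interferon genes, 22 were higher in sub-cluster 6, or 23 in either direction adjusted over the list alone (camera adjusted p = 2.81e-31, and adjusted p = 0.241 with an estimated correlation). Of 2773 genes called between sub-clusters 1 and 2 and tested in both pairs, 72.0% kept their sign. Of 1003 called in both pairs, 910 had the same sign. With independent calls, 252 of the 9229 genes tested in both pairs would be called in both with the same sign. Sub-cluster 8 was set beside sub-cluster 1 by its higher Clca3a1, and both pairs came from 1 clustering of the same libraries. Some of the agreement was thus built in. Of 21 immediate early genes, 5 were higher in sub-cluster 6 and 0 in sub-cluster 8. The list's camera adjusted p was 0.00130, and 0.498 with an estimated correlation. In the first pair 8 were higher in sub-cluster 1 and 5 in sub-cluster 2. The share of 72.0% with the same sign lies between the values set for an immediate early response and for its absence. That response and a difference of LEC type thus cannot be told apart for these genes.

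Other splits of the 6 sums are too few for a share under 0.05, since 1 of 10 is the real split. Each other split also mixes both classes in each group, and the classes were made from the same counts. Low counts in the other splits were thus built in and decide nothing. For LEC-like against BEC-like cells the real split called 2940 genes in edgeR and the highest other 0 (385 at an unadjusted p under 0.05). For sub-clusters 1 and 2 the counts were 2890 and 0 (228 unadjusted), and for the low-Fos pair 1678 and 0 (259 unadjusted).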
